A study of Homo sapiens with 9 samples.

How the data were processed

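The input table listed 30438 genes with, for each of 9 libraries, a column of deposited counts and a column of deposited FPKM values. Per the labels, RNA was extracted with Trizol, had a RIN above 7, was selected for poly(A) with oligo(dT), and was made into stranded libraries by the dUTP method. They were sequenced as paired 150-base reads on an Illumina NovaSeq instrument. The submitters' processing notes name HISAT2 for alignment; its version, the counting program, the genome build and the annotation are not given in the sources used here. Reads were not realigned. The counts were whole numbers, and for the 1307 genes with high counts in all libraries 99.87% of ratios of FPKM to count lay within 0.1% of the library median. The deposited FPKM were thus the deposited counts rescaled by the authors. Library totals ran from 49.6 to 66.2 M counts; for genes at a few CPM the SD of 3 libraries can lie below the counting error. Of the gene identifiers 28967 were also in GENCODE v29, and 28929 of them overlapped it on the same chromosome, but only 14244 had identical start and end, so exact positions hang on an annotation that is not known. For 161 duplicated symbols the row with the larger total was used in gene lists. Of all genes, 7034 carried only an Ensembl identifier.

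The comparisons, tests, alternatives, gene lists and rules for naming genes were written before the data were examined. The plan set edgeR on counts as the main test if the table held counts, which it did. Genes were filtered with filterByExpr (minimum count 10, minimum total 15), which left 18202, and scaled by TMM. One edgeR quasi-likelihood fit of all 9 libraries with 1 mean per gel gave the 3 comparisons, 2-sided, with Benjamini-Hochberg adjustment over all genes tested, a threshold of 0.05 and no fold minimum. Fold changes are log2 of the first gel named over the second, CPM are counts scaled to TMM-adjusted library size, and errors are SD unless SE is written. Replicate number was not used as a factor. A first run used the newer quasi-likelihood method of edgeR, which called 2 genes for BNP-PEDOT-PSF-AG against AG; after this was seen the fit was reset to the default of the installed version, and the newer method was kept as an alternative.

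Lists with at least 3 tested members were tested with camera of limma on the edgeR residual z-scores of the counts at its preset correlation of 0.01, adjusted over 26 lists. Beside it stood camera with an estimated correlation and fry, a rotation test. Both called 0 lists in each comparison; fry for changes in either direction called 0, 8 and 3 for PEDOT-PSF-AG against AG, BNP-PEDOT-PSF-AG against AG and BNP-PEDOT-PSF-AG against PEDOT-PSF-AG. The lists were written from general knowledge and covered pro-inflammatory cytokines, alternative activation, the NF-kB pathway, interferon-stimulated genes, NRF2 targets, NADPH oxidase and oxidant defence, metallothioneins, heat shock, the integrated stress and unfolded protein responses, hydrogen sulfide metabolism, glycolysis, hypoxia and nuclear oxidative phosphorylation. They also covered mitochondrially encoded genes, the cell cycle, cholesterol synthesis, lipid efflux, extracellular matrix, growth factors, MHC class II, the inflammasome, lysosome and phagocytosis, Toll-like receptors, iron, ion channels, and apoptosis. Another 12 lists of cell type and quality markers were described without a test of the list.

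By the planned rule, named genes were the 10 largest fold changes per direction past the threshold with groups apart, a mean FPKM of at least 5 in the higher group and a symbol, up to 4 members past the threshold per list, and 14 fixed genes. Of these MRC1 was not tested. No gene passed, so a rule chosen after the values were seen named the 10 protein-coding genes per direction with the lowest p, groups apart and a mean of at least 5 CPM in the higher group; other genes named in the text are members of the lists, called or not, or markers, picked after the values were seen. Where a gel had 0 counts in all libraries, a bound of 3 counts over the group replaced the fitted fold. Some single-gene results are not reported here.

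DESeq2 (adjusted p not given for 55, 3930 and 4280 genes in the 3 comparisons) and limma on log2(FPKM + 1) for genes with an FPKM of at least 1 in 3 libraries were the other tools. Further alternatives were pseudocounts of 0.1 and 5, other filters, upper quartile, quantile and DESeq2 scaling, a robust variance prior, a fold minimum, a replicate block, fits of only the 6 libraries compared, and the omission of each library in turn. No library was left out of the main fit. Shares of single libraries were compared by exact permutation of the 3 against 3 libraries. A correction for gene length and GC content, chosen after seeing the data, used spline offsets with 4 degrees of freedom in each library; a GC value was at hand for 17758 of the tested genes (97.6%).

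The tests were tried on self-made counts with the spread of these libraries. In 3 runs edgeR found 13, 20 and 27 of 100 genes changed 2-fold and 96, 94 and 94 of 100 changed 4-fold, with 7, 8 and 10 false calls. A 2-fold change of a single gene would thus mostly be missed. The changed genes were drawn from those with a mean of at least 5 CPM, and each gene had the same spread in all gels. The runs thus do not show that 4-fold changes were absent from the real data. SLC2A5 had a log2 fold change of −2.15 for BNP-PEDOT-PSF-AG against AG and was not called (edgeR adjusted p = 0.0697). Camera called a glycolysis list shifted 2-fold in each run and 0 other lists. The simulated genes were drawn independently, so this cannot show how often camera falsely calls lists whose genes vary together. In the real data estimated correlations ran from −0.0569 for metallothioneins to 0.734 for the cell cycle between PEDOT-PSF-AG and AG. With the length and GC correction, edgeR found 14, 19 and 29 of 100 genes changed 2-fold and 96, 95 and 94 changed 4-fold. R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, the data.table package (1.17.8), Python 3.11.15 and matplotlib 3.10.9 were used.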

Results

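Gene expression was measured by RNA sequencing in THP-1 cells, a human monocytic leukaemia line labelled here as macrophage. The cells were kept for 3 days in medium with 33 mM glucose and 100 µg/L lipopolysaccharide (LPS), a bacterial wall component that activates macrophages. The cultures lay on 3 hydrogels named AG, PEDOT-PSF-AG and BNP-PEDOT-PSF-AG in the labels, with 3 libraries per gel and 9 in all. PEDOT is a conducting polymer, and the labels do not spell out the other abbreviations. The stated purpose was to learn what the BNP-PEDOT-PSF-AG gel does. That design gives 3 comparisons: PEDOT-PSF-AG against AG, BNP-PEDOT-PSF-AG against AG, and BNP-PEDOT-PSF-AG against PEDOT-PSF-AG. No untreated or LPS-free culture was analysed here. Libraries held 58.1, 57.8 and 65.2 M counts on AG, 60.8, 61.8 and 64.4 M on PEDOT-PSF-AG, and 66.2, 53.5 and 49.6 M on BNP-PEDOT-PSF-AG. The labels do not say whether replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical. Gene positions are given as in the deposited table, whose genome build is not given in the sources used here.

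A few transcripts took a larger share of the BNP-PEDOT-PSF-AG libraries. CXCL8, the neutrophil chemokine interleukin-8, made up 5.8 ± 2.83% of counts on BNP-PEDOT-PSF-AG, 1.62 ± 0.571% on AG and 1.89 ± 0.799% on PEDOT-PSF-AG (SD, n = 3). The mitochondrial ribosomal RNAs MT-RNR1 and MT-RNR2 together made up 1.53 ± 0.0579%, 0.548 ± 0.18% and 0.654 ± 0.164% in the same order. For both shares all BNP-PEDOT-PSF-AG libraries lay above all others, and the exact permutation p against either gel was 0.1, the smallest that 3 against 3 allows (2-sided; 0.3 after Benjamini-Hochberg adjustment over 18 tests). For CXCL8 the gap was narrow, at 2.897% in BNP-PEDOT-PSF-AG 1 and 2.802% in PEDOT-PSF-AG 1. The higher CXCL8 shares were those of BNP-PEDOT-PSF-AG 2 and 3, at 8.556% and 5.938%. Mitochondrial messenger RNAs made up 1.51 ± 0.443% on BNP-PEDOT-PSF-AG and 1.75 ± 0.397% on AG (exact permutation p = 0.6). Genes with an FPKM of at least 1 numbered 9970 ± 200, 10100 ± 202 and 9950 ± 107 on AG, PEDOT-PSF-AG and BNP-PEDOT-PSF-AG.

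The libraries of a gel were not alike. BNP-PEDOT-PSF-AG 1 correlated at 0.976 with AG 1 and with PEDOT-PSF-AG 1, and at 0.923 with BNP-PEDOT-PSF-AG 2 and 3, which correlated at 0.966 with each other (Pearson's r of log2 CPM across genes, which are not independent). The first principal component (42.9% of the variance) placed BNP-PEDOT-PSF-AG 2 and 3 at 108.2 and 105.2 and PEDOT-PSF-AG 2 at 31.9, with the other 6 libraries between −58.3 and −8.1. Epithelial markers summed to 189 and 136 CPM in BNP-PEDOT-PSF-AG 2 and 3 and to 93.8 CPM in PEDOT-PSF-AG 2, against at most 2.37 CPM in the rest. Most of each sum came from KRT8 and KRT18, keratins of simple epithelia. KRT8 was at 102, 73.5 and 54 CPM in those libraries and below 1 CPM in the other 6. KRT18 was at 78.0, 59.0 and 37.3 CPM in those libraries. EPCAM was at only 1.18, 0.292 and 0.135 CPM there, and CDH1 at 0.649, 0.375 and 0.675 CPM. Where epithelial markers are named below, mainly these keratins are meant. The fibroblast collagen gene COL1A2 stood at 61.8 and 43.0 CPM in AG 2 and 3 and at 0.809 CPM in AG 1. COL1A1 was at 91.9, 95.2 and 116 CPM in PEDOT-PSF-AG 2 and BNP-PEDOT-PSF-AG 2 and 3, at 56.28 and 28.99 CPM in AG 2 and 3, and between 6.79 and 13.4 CPM in the rest. Fibroblast markers as a list summed to 215, 342 and 230 CPM on AG, 177, 276 and 222 CPM on PEDOT-PSF-AG, and 177, 168 and 213 CPM on BNP-PEDOT-PSF-AG, so only some of them set libraries apart; PDGFRA was at 54.37 CPM or more in all 9. COL1A2 and KRT8 were both under 1 CPM in AG 1, PEDOT-PSF-AG 1 and 3 and BNP-PEDOT-PSF-AG 1. Differentiated macrophage markers summed to 4270, 4270 and 4230 CPM on AG, 3690, 3640 and 3950 CPM on PEDOT-PSF-AG, and 3380, 2870 and 3460 CPM on BNP-PEDOT-PSF-AG. The largest members tested, SPP1 and CSF1R, were at 1600 ± 382 and 944 ± 233 CPM on AG and at 1040 ± 112 and 738 ± 141 CPM on BNP-PEDOT-PSF-AG. CD14 and CD68 were at 207 ± 13.3 and 412 ± 20 CPM on AG and at 193 ± 18.4 and 406 ± 31.5 CPM on BNP-PEDOT-PSF-AG. ACP5 and APOC1 had higher means on BNP-PEDOT-PSF-AG than on AG. The ribosomal protein genes RPL7 and RPS27 were at 3881 and 1217 CPM in BNP-PEDOT-PSF-AG 2 and at 2561 and 916.1 CPM in BNP-PEDOT-PSF-AG 3, against at most 1576 and 514.3 CPM in the rest. As a list, ribosomal protein genes summed to 19700 and 16800 CPM in BNP-PEDOT-PSF-AG 2 and 3, against 18300 CPM in AG 3 and 15500 CPM in PEDOT-PSF-AG 1. Only some of them thus set these libraries apart. No member of the 12 marker lists passed the edgeR threshold in any comparison.

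**Figure D1:**
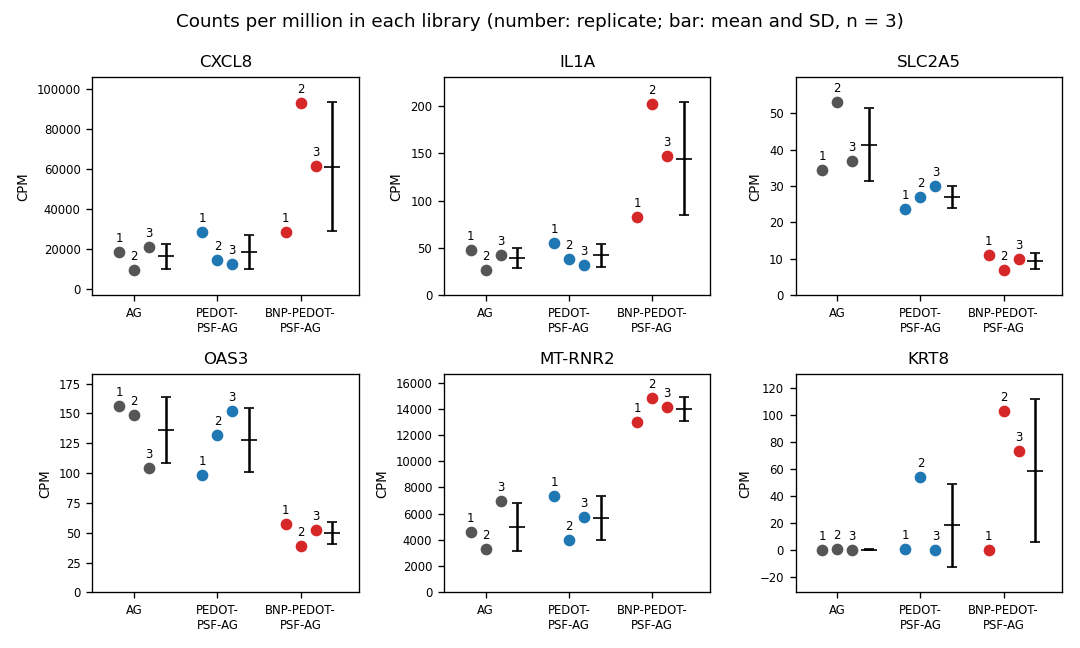
CPM (vertical axis) of CXCL8, IL1A, SLC2A5, OAS3, MT-RNR2 and KRT8 in each library by gel, with dots numbered by replicate and bars for the mean ± SD (n = 3). KRT8 was at 54 CPM in PEDOT-PSF-AG 2 and at 102 and 73.5 CPM in BNP-PEDOT-PSF-AG 2 and 3, while MT-RNR2 was at 13000 CPM or more in each BNP-PEDOT-PSF-AG library.

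The comparison of PEDOT-PSF-AG with AG addressed the addition of PEDOT and PSF to the gel. Glycolysis genes fell as a list on PEDOT-PSF-AG in limma's camera test (21 of 23 tested members below 0, median log2 fold change −0.21; adjusted p = 1.36e-05; adjusted p = 0.206 with an estimated correlation, where the call was lost). ALDOC, an aldolase, was at 55.7 ± 4.16 CPM on PEDOT-PSF-AG and 86.9 ± 13.2 CPM on AG (SD, n = 3), and ALDOA, ENO1 and GAPDH had log2 fold changes of −0.43, −0.28 and −0.29. Lysosome and phagocytosis genes fell too (median −0.20, 21 of 26 below 0; camera adjusted p = 0.000387; adjusted p = 0.206 with an estimated correlation), with CTSB, a cathepsin protease, at 995 ± 66.4 against 1260 ± 264 CPM and the macrophage glycoprotein CD68 at a log2 fold change of −0.26. MHC class II genes, which present antigen, fell as a list of 9 (median −0.32, 7 below 0; camera adjusted p = 0.00144; adjusted p = 0.206 with an estimated correlation), with CD74 at 124 ± 17.7 against 152 ± 12.6 CPM. Cell cycle genes rose as a list (median 0.41, 30 of 32 above 0; camera adjusted p = 0.00034; adjusted p = 0.494 with an estimated correlation), with the mitotic kinesin KIF23 at 11.5 ± 1.73 against 6.85 ± 0.868 CPM.

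All 4 list calls were thus lost when the correlation of the genes was estimated. Adjusted over the list alone, 0 members of these 4 lists passed. With 1 library left out the lysosome median ran from −0.28 (without PEDOT-PSF-AG 3) to −0.08 (without AG 2) and the MHC class II median from −0.58 (without AG 1) to −0.07 (without AG 3). The cell cycle call was lost without PEDOT-PSF-AG 2 (limma's camera adjusted p = 0.863, median −0.01) and without AG 1 (0.057). TOP2A, a topoisomerase of dividing cells, was at 6.77, 18.04 and 6.45 CPM in PEDOT-PSF-AG 1, 2 and 3, and PEDOT-PSF-AG 2 was the library of this gel with epithelial markers.

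Extracellular matrix genes fell on PEDOT-PSF-AG (median −0.13, 19 of 24 below 0; camera adjusted p = 0.000387; adjusted p = 0.206 with an estimated correlation), with 1 member passing adjusted over the list alone (0 to 3 with 1 library left out). CTSK, a collagen-degrading cathepsin, was at 3.47, 19.7 and 40.4 CPM in AG 1, 2 and 3 and at 3.41 ± 0.681 CPM on PEDOT-PSF-AG. MMP2, a gelatinase, was at 45.4 ± 21.7 and 20.4 ± 5.30 CPM, and was highest in AG 2 and 3, the libraries highest in COL1A2. Lipid efflux and handling genes fell (median −0.15, 16 of 22 below 0; camera adjusted p = 0.0115; adjusted p = 0.206 with an estimated correlation), with the cholesterol exporter ABCG1 at 15.7 ± 5.42 against 25.1 ± 4.99 CPM. Alternative activation genes fell (median −0.16, 18 of 24 below 0; camera adjusted p = 0.00946; adjusted p = 0.206 with an estimated correlation), with log2 fold changes of −0.91 for the scavenger receptor MARCO and −0.52 for TREM2. Pro-inflammatory genes (median −0.18, 21 of 33 below 0) and ion channel genes (median −0.15, 20 of 27 below 0) fell at a camera adjusted p of 0.0475 each (adjusted p = 0.413 with an estimated correlation for both). CCL5, a chemokine, was at 2320 ± 363 against 3440 ± 1180 CPM. Adjusted over the list alone, 0 members of these last 4 lists passed. The calls were lost without AG 3 (0.113) and PEDOT-PSF-AG 2 (0.122) for lipid handling, and without any 1 of AG 1, AG 2, AG 3, PEDOT-PSF-AG 1 and PEDOT-PSF-AG 2 (0.057, 0.0736, 0.0823, 0.313 and 0.0619) for alternative activation. They were lost without AG 1, AG 3, PEDOT-PSF-AG 2 or PEDOT-PSF-AG 3 (0.106, 0.76, 0.257 and 0.522) for the pro-inflammatory list, and without AG 2, PEDOT-PSF-AG 1 or PEDOT-PSF-AG 2 (0.4, 0.658 and 0.0851) for ion channels. With 1 library left out the medians ran from −0.25 (without AG 1) to −0.14 (without AG 3) for extracellular matrix, −0.27 (AG 1) to −0.12 (AG 3) for lipid handling and −0.35 (PEDOT-PSF-AG 3) to −0.11 (AG 2) for alternative activation. They ran from −0.30 (PEDOT-PSF-AG 1) to −0.02 (AG 3) for the pro-inflammatory list and −0.24 (PEDOT-PSF-AG 3) to −0.03 (AG 2) for ion channels. With CACNA1C, which had 0 counts on PEDOT-PSF-AG, placed at its bound of 3 counts over the group, the ion channel median was still −0.15.

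Single genes did not pass the threshold between PEDOT-PSF-AG and AG. edgeR called 0 of 18202 genes (lowest adjusted p = 1), with 267 at an unadjusted p under 0.05 (127 higher, 140 lower; 910 by chance), while DESeq2 called 14 and limma on log2(FPKM + 1) called 0. Groups did not overlap for 1254 genes (6.89%, against 10% by chance). DCN (decorin, ENSG00000011465, chromosome 12 from 91140484 to 91182817), a fibroblast proteoglycan, had a log2 fold change of −6.28 (SE 1.14; edgeR adjusted p = 1), at 0.286, 13.9 and 17.6 CPM in AG 1, 2 and 3 and 0.134 ± 0.0271 CPM on PEDOT-PSF-AG. Among the fixed genes, log2 fold changes ran from −0.23 for the angiogenic factor VEGFA to 0.22 for the scavenger receptor CD163, with TNF at −0.08, IL1B at −0.16 and IL6 at −0.20. Without AG 1, PEDOT-PSF-AG 2 or PEDOT-PSF-AG 3 edgeR called 3, 2 and 1 genes, and without PEDOT-PSF-AG 2 the lists called went from 9 to 5. In the 4 libraries under 1 CPM of both COL1A2 and KRT8, chosen after seeing the data, none of the 9 lists passed, but AG has only 1 library there.

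The remaining lists did not pass between PEDOT-PSF-AG and AG. Interferon-stimulated genes had a median of −0.11 (camera adjusted p = 0.0871), heat shock genes 0.11 (0.0508), metallothioneins −0.29 (0.0651), nuclear oxidative phosphorylation genes −0.11 (0.0651) and hydrogen sulfide metabolism genes −0.26 (0.124). NF-kB pathway genes (−0.10), NADPH oxidase genes (−0.19), stress response genes (−0.08), hypoxia genes (−0.08), mitochondrially encoded genes (−0.04), cholesterol synthesis genes (−0.13), growth factors (−0.11), inflammasome genes (−0.10) and iron genes (−0.16) had adjusted p-values from 0.0871 to 0.722. Median, mean and test differed in sign for NRF2 targets (−0.06, 0.58 and up; 0.771), Toll-like receptors (−0.01, 0.08 and up; 0.483) and apoptosis genes (0.10, −0.02 and up; 0.722). For cholesterol synthesis the mean lay above 0, with the median and the test below. These medians were not stable: with 1 library left out 16 of the 17 moved by over 1.5 times or lost their sign in at least 1 fit, and 8 were seen on both sides of 0. The oxidative phosphorylation median ran from −0.35 (without PEDOT-PSF-AG 1) to 0.16 (without AG 3), the interferon median from −0.26 (AG 2) to 0.08 (AG 1), the mitochondrially encoded from −0.21 (AG 1) to 0.12 (AG 2), and the hydrogen sulfide median was −0.06 without AG 3.

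The comparison of BNP-PEDOT-PSF-AG with AG set the complete gel against the plain one. Interferon-stimulated genes fell as a list on BNP-PEDOT-PSF-AG (34 of 40 below 0, median log2 fold change −0.62; limma's camera adjusted p = 1.97e-13; adjusted p = 0.299 with an estimated correlation, where the call was lost). OAS3, an antiviral 2'-5'-oligoadenylate synthetase, was at 49.8 ± 9.50 CPM on BNP-PEDOT-PSF-AG and 136 ± 27.8 CPM on AG (SD, n = 3), and OAS2 was at 24.8 ± 5.23 and 62.3 ± 11.8 CPM. MX2, an antiviral GTPase, was at 12.3 ± 3.98 and 28.0 ± 3.10 CPM. Glycolysis genes fell with all 23 below 0 (median −0.35; camera adjusted p = 1.34e-06; adjusted p = 0.299 with an estimated correlation), including the glucose transporter SLC2A1 at 190 ± 14.9 against 335 ± 77.4 CPM and lactate dehydrogenase LDHA at 975 ± 263 against 1500 ± 158 CPM. Cell cycle genes rose (median 1.24, 30 of 32 above 0; camera adjusted p = 1.62e-07; adjusted p = 0.467 with an estimated correlation), with TOP2A at 21.6 ± 14.7 against 5.04 ± 0.881 CPM.

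All 3 list calls were thus lost when the correlation of the genes was estimated. Adjusted over the list alone, 11 interferon-stimulated, 0 glycolysis and 2 cell cycle genes passed, but these counts hung on single libraries. Without BNP-PEDOT-PSF-AG 1 they were 14, 9 and 26, and over all omissions of 1 library they ran from 6 to 21, 0 to 9 and 0 to 26. Of the interferon-stimulated genes 13 had all BNP-PEDOT-PSF-AG libraries below all AG libraries, while ISG15 and IFI44 had log2 fold changes of 0.12 and 0.34. The 3 calls held without any 1 library, but the interferon median was −0.38 without AG 1 and the glycolysis median −0.19 without BNP-PEDOT-PSF-AG 1. In the 4 libraries under 1 CPM of both COL1A2 and KRT8 the camera direction of the cell cycle list was down, but AG and BNP-PEDOT-PSF-AG have 1 library each there, so no gel difference can be called. TOP2A was at 4.70, 28.8 and 31.2 CPM in BNP-PEDOT-PSF-AG 1, 2 and 3, and the last 2 carried epithelial markers.

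Hypoxia response genes fell on BNP-PEDOT-PSF-AG (median −0.32, 18 of 20 below 0; camera adjusted p = 0.00335; adjusted p = 0.467 with an estimated correlation), with NDRG1 at 227 ± 26.8 against 375 ± 64.0 CPM. ADM, the vasodilator adrenomedullin, was at 6.70 ± 0.115 against 13.4 ± 2.40 CPM. Extracellular matrix genes fell (median −0.38, 20 of 24 below 0; camera adjusted p = 3.56e-06; adjusted p = 0.299 with an estimated correlation), with the stromelysins MMP3 and MMP10 at 99.9 ± 28.6 against 215 ± 66.8 CPM and 72.1 ± 35.1 against 174 ± 51.2 CPM. CTSK and THBS1 in this list were highest in AG 2 and 3, the libraries highest in COL1A2. Lysosome and phagocytosis genes fell (median −0.11, 20 of 26 below 0; camera adjusted p = 0.0397; adjusted p = 0.467 with an estimated correlation), with the integrin ITGB2 at 2380 ± 176 against 3550 ± 887 CPM. Nuclear oxidative phosphorylation genes rose (median 0.18, 23 of 34 above 0; camera adjusted p = 0.0397; adjusted p = 0.701 with an estimated correlation). UQCRB, a subunit of respiratory complex III, was at 268.5, 1050 and 730 CPM in BNP-PEDOT-PSF-AG 1, 2 and 3 against 219 ± 71.6 CPM on AG. RPL7 and RPS27 were also highest in BNP-PEDOT-PSF-AG 2 and 3, while the sum of the ribosomal protein list did not set both libraries apart. Adjusted over the list alone, 4 hypoxia, 3 matrix, 0 lysosome and 0 oxidative phosphorylation genes passed. Without BNP-PEDOT-PSF-AG 1 these counts were 9, 7, 0 and 7, and without other single libraries they fell to as few as 1, 0, 0 and 0. The hypoxia call was lost without BNP-PEDOT-PSF-AG 3 (0.084). The lysosome call was lost without AG 2, AG 3, BNP-PEDOT-PSF-AG 1 or BNP-PEDOT-PSF-AG 2 (0.162, 0.0749, 0.103 and 0.0754), and the oxidative phosphorylation call without AG 1, AG 2, BNP-PEDOT-PSF-AG 2 or BNP-PEDOT-PSF-AG 3 (0.184, 0.803, 0.189 and 0.0796). With 1 library left out the oxidative phosphorylation median ran from 0.01 (without AG 2) to 0.46 (without AG 3), with 0.35 without BNP-PEDOT-PSF-AG 1. The lysosome median ran from −0.28 (without BNP-PEDOT-PSF-AG 1) to −0.07 (without AG 2), and the hypoxia median was −0.21 without AG 2 and without BNP-PEDOT-PSF-AG 3.

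**Figure D2:**
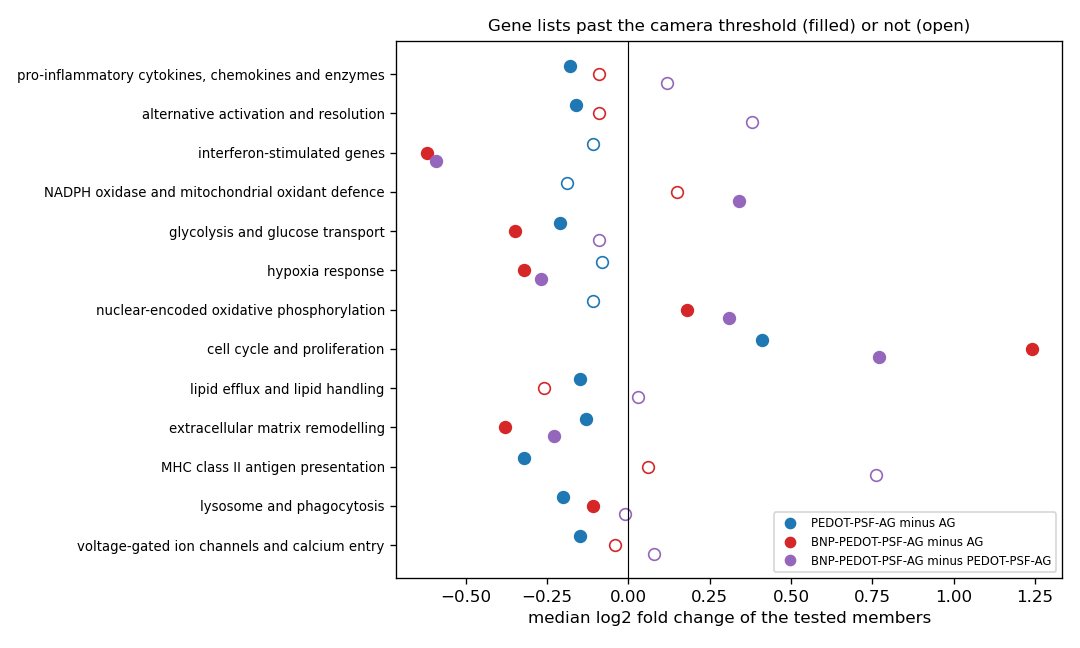
Median log2 fold change of the tested members (horizontal axis) of the gene lists past the camera threshold in at least 1 comparison (vertical axis), one colour per comparison, filled where the list passed and open where it did not. Interferon-stimulated genes had medians of −0.62 and −0.59 for BNP-PEDOT-PSF-AG against AG and against PEDOT-PSF-AG, and cell cycle genes had medians of 0.41, 1.24 and 0.77 in the 3 comparisons.

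Of single genes none passed the edgeR threshold between BNP-PEDOT-PSF-AG and AG, and the values of some follow. CXCL8 (ENSG00000169429, chromosome 4 from 73740519 to 73743715) had a log2 fold change of 1.90 (SE 0.45; edgeR adjusted p = 0.234), from 16300 ± 6130 CPM on AG to 61000 ± 32100 CPM on BNP-PEDOT-PSF-AG (SD, n = 3). IL1A (ENSG00000115008, chromosome 2 from 112773925 to 112784493), an alarmin cytokine, stood at 39.1 ± 10.5 and 144 ± 59.7 CPM (log2 fold change 1.88, SE 0.35, edgeR adjusted p = 0.212). SLC2A5 (ENSG00000142583, chromosome 1 from 9035106 to 9088457), a fructose transporter, was at 41.4 ± 10.1 and 9.32 ± 2.22 CPM (log2 fold change −2.15, SE 0.25, edgeR adjusted p = 0.0697). TREM1, which amplifies inflammatory signalling in myeloid cells, was at 15.1 ± 1.69 and 5.29 ± 1.54 CPM. NLRP3 (ENSG00000162711, chromosome 1 from 247416156 to 247449108), an inflammasome sensor, had a log2 fold change of −0.74 (SE 0.22; edgeR adjusted p = 0.272). CD163 (ENSG00000177575, chromosome 12 from 7470813 to 7503893) was at −0.96 (SE 0.32; edgeR adjusted p = 0.285). OAS3 (ENSG00000111331) and OAS2 (ENSG00000111335) lie on chromosome 12 from 112938051 to 112973251 and from 112978395 to 113011723. TNF was at 675 ± 97.2 and 833 ± 89.8 CPM (log2 fold change 0.30), IL6 at 42.0 ± 7.06 and 29.7 ± 12.4 CPM (−0.50), and IL1B at 14500 ± 3600 and 14500 ± 4670 CPM (0.01). VEGFA, SOD2, NQO1, CCL2, TGFB1 and HMOX1 had log2 fold changes of −0.29, −0.20, 0.12, −0.10, 0.10 and −0.04, and IL10 of 0.74 (SE 0.40; edgeR adjusted p = 0.431).

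edgeR called 0 of 18202 genes between BNP-PEDOT-PSF-AG and AG, with 2493 at an unadjusted p under 0.05 (1601 higher, 892 lower; 910 by chance), while DESeq2 called 482 (384 higher, 98 lower) and limma on log2(FPKM + 1) called 6. Groups did not overlap for 2815 genes (15.5%, against 10% by chance). Leaving out BNP-PEDOT-PSF-AG 1 raised the edgeR count to 1346 (730 higher, 616 lower), and leaving out AG 1 gave 1. Without BNP-PEDOT-PSF-AG 1, CXCL8, IL1A, SLC2A5, OAS3, NLRP3 and CD163 passed (edgeR adjusted p from 0.0178 to 0.0326).

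Several lists did not pass camera between BNP-PEDOT-PSF-AG and AG. Of these, limma's fry for changes in either direction passed the pro-inflammatory list (adjusted p = 0.00876), metallothioneins (0.00869), alternative activation (0.0108) and growth factors (0.018). The pro-inflammatory list had 5 members at an unadjusted p under 0.05 above 0 and 2 below (median −0.09, mean −0.06, test up, camera adjusted p = 0.677). Hydrogen sulfide metabolism genes had a median of 0.06 (0.623). MPST and TST, sulfurtransferases, had log2 fold changes of 0.82 and 0.54, and the list members CBS and CTH of −0.04 and −0.03. NRF2 targets had a median of 0.07 and a mean of 0.99 (0.128), where AKR1B10, AKR1C2 and AKR1C3 were high only in the libraries with epithelial markers. Medians were −0.09 for alternative activation (0.0769; also −0.09 with STAB1, 0 counts on BNP-PEDOT-PSF-AG, at its bound), −0.13 for the NF-kB pathway (0.104), 0.15 for NADPH oxidase (0.19), −0.49 for metallothioneins (0.19), 0.03 for heat shock (0.623), 0 for cholesterol synthesis (0.623) and −0.13 for mitochondrially encoded genes (0.234). They were 0.06 for MHC class II (0.87), 0.29 for the inflammasome (0.373), −0.10 for Toll-like receptors (0.463) and −0.04 for ion channels (0.338). Median, mean and test differed in sign for the stress response (−0.13, 0.07 and down; 0.338), lipid handling (−0.26, 0.06 and down; 0.19), growth factors (0.18, 0.09 and down; 0.784), iron (−0.04, 0.03 and down; 0.549) and apoptosis genes (−0.15, 0.07 and down; 0.711).

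The medians of these lists were not stable either. With 1 library left out 18 of the 19 moved by over 1.5 times or lost their sign in at least 1 fit between BNP-PEDOT-PSF-AG and AG, and 9 were seen on both sides of 0. The Toll-like receptor median ran from −0.53 (without BNP-PEDOT-PSF-AG 1) to 0.03 (without AG 2), the pro-inflammatory from −0.27 (BNP-PEDOT-PSF-AG 1) to 0.03 (AG 3), and NADPH oxidase from 0.02 (BNP-PEDOT-PSF-AG 2) to 0.36 (BNP-PEDOT-PSF-AG 1). The inflammasome ran from 0.12 (AG 2) to 0.45 (BNP-PEDOT-PSF-AG 1), ion channels from −0.14 (BNP-PEDOT-PSF-AG 2) to 0.10 (BNP-PEDOT-PSF-AG 1), hydrogen sulfide metabolism from −0.12 (BNP-PEDOT-PSF-AG 2) to 0.23 (AG 1), MHC class II from −0.09 (BNP-PEDOT-PSF-AG 2) to 0.19 (AG 3), growth factors from −0.02 (BNP-PEDOT-PSF-AG 1) to 0.30 (BNP-PEDOT-PSF-AG 3), apoptosis from −0.32 (BNP-PEDOT-PSF-AG 1) to −0.05 (AG 1) and mitochondrially encoded genes from −0.30 (AG 1) to −0.02 (AG 2).

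The comparison of BNP-PEDOT-PSF-AG with PEDOT-PSF-AG addressed the addition of BNP. Interferon-stimulated genes fell again (32 of 40 below 0, median −0.59; limma's camera adjusted p = 3.1e-10; adjusted p = 0.523 with an estimated correlation, where the call was lost). OAS3 was at 49.8 ± 9.50 against 128 ± 26.9 CPM and OAS2 at 24.8 ± 5.23 against 55.5 ± 3.83 CPM (SD, n = 3). Oxidative phosphorylation genes of the nucleus rose (median 0.31, 27 of 34 above 0; camera adjusted p = 0.0012; adjusted p = 0.697 with an estimated correlation), among them NDUFB3 of respiratory complex I at 41.5, 142 and 117 CPM in BNP-PEDOT-PSF-AG 1, 2 and 3 against 38.9 ± 16.6 CPM. NADPH oxidase and oxidant defence genes rose (median 0.34, 11 of 15 above 0; camera adjusted p = 0.0396; adjusted p = 0.523 with an estimated correlation), with the oxidase subunit NCF1 at 210.3, 392.2 and 453.2 CPM in BNP-PEDOT-PSF-AG 1, 2 and 3 against 170 ± 18.5 CPM and glutaredoxin GLRX at 39.06, 119.9 and 81.94 against 26.6 ± 5.80 CPM. BNP-PEDOT-PSF-AG 2 and 3, the higher libraries for these genes, carried epithelial markers. NCF1 has near-identical pseudogene copies, so its value is uncertain.

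None of the 3 calls held with the correlation of the genes estimated. Adjusted over the list alone, 12 interferon-stimulated, 0 oxidative phosphorylation and 2 NADPH oxidase genes passed. Without BNP-PEDOT-PSF-AG 1 these counts were 17, 11 and 11, and without other single libraries they fell to as few as 2, 0 and 0. The interferon call held without any 1 library. The oxidative phosphorylation call was lost without PEDOT-PSF-AG 3 (0.054), and the NADPH oxidase call without PEDOT-PSF-AG 1, 2 or 3 (0.0651, 0.125 and 0.054) or BNP-PEDOT-PSF-AG 2 (0.0928). With 1 library left out the NADPH oxidase median ran from 0.21 (without BNP-PEDOT-PSF-AG 2 or 3) to 0.56 (without BNP-PEDOT-PSF-AG 1), and the oxidative phosphorylation median from 0.21 (without PEDOT-PSF-AG 3) to 0.53 (without PEDOT-PSF-AG 1).

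Hypoxia genes fell on BNP-PEDOT-PSF-AG relative to PEDOT-PSF-AG (median −0.27, 16 of 20 below 0; camera adjusted p = 0.021), with BNIP3, a mitophagy receptor, at 85.4 ± 19.1 against 129 ± 27.2 CPM. Extracellular matrix genes fell (median −0.23, 16 of 24 below 0; camera adjusted p = 0.039), with TGFBI at 78.2 ± 15.5 against 142 ± 26.6 CPM. Both had an adjusted p = 0.523 with an estimated correlation. Cell cycle genes rose (median 0.77, 29 of 32 above 0; camera adjusted p = 0.00585; adjusted p = 0.769 with an estimated correlation), with CENPE, a kinetochore motor, at 4.20 ± 1.85 against 1.32 ± 0.274 CPM. Adjusted over the list alone, 0 hypoxia, 0 matrix and 1 cell cycle genes passed. Without BNP-PEDOT-PSF-AG 1 these counts were 8, 7 and 21, and the cell cycle count fell to 0 without other single libraries. Calls were lost without PEDOT-PSF-AG 1, BNP-PEDOT-PSF-AG 2 or BNP-PEDOT-PSF-AG 3 for hypoxia (0.0696, 0.0928 and 0.133) and without PEDOT-PSF-AG 3 or BNP-PEDOT-PSF-AG 2 for matrix genes (0.054 and 0.0984). The cell cycle call was lost without PEDOT-PSF-AG 1, PEDOT-PSF-AG 3, BNP-PEDOT-PSF-AG 2 or BNP-PEDOT-PSF-AG 3 (0.165, 0.054, 0.218 and 0.189), and its median ran from 0.46 (without BNP-PEDOT-PSF-AG 2) to 1.28 (without PEDOT-PSF-AG 2), with 1.21 without BNP-PEDOT-PSF-AG 1. The hypoxia median was −0.14 without BNP-PEDOT-PSF-AG 3, and the matrix median −0.14 without PEDOT-PSF-AG 3 or BNP-PEDOT-PSF-AG 2. Lists called went from 6 to 2 without PEDOT-PSF-AG 3 and to 2 without BNP-PEDOT-PSF-AG 2. In the 4 libraries under 1 CPM of both COL1A2 and KRT8 the camera direction of the cell cycle list was down again, with 1 BNP-PEDOT-PSF-AG library and no gel difference to be called.

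Single genes again did not pass. CXCL8 had a log2 fold change of 1.72 (SE 0.45) from 18500 ± 8560 CPM on PEDOT-PSF-AG, IL1A of 1.77 (SE 0.35) from 42.3 ± 11.9 CPM and SLC2A5 of −1.53 (SE 0.25) from 26.9 ± 3.07 CPM, each at an edgeR adjusted p of 0.409. ANKRD1, an ankyrin repeat protein, was at 15.0 ± 5.60 and 53.5 ± 17.5 CPM, CSF3, the granulocyte colony-stimulating factor, at 32.7 ± 2.36 and 65.6 ± 16.4 CPM, and PTGES, a prostaglandin E synthase, at 7.41 ± 0.442 and 16.9 ± 5.92 CPM. CD163 had a log2 fold change of −1.18 (SE 0.32) and NLRP3 of −0.61 (SE 0.22), while TNF and IL1B were at 0.38 and 0.17. edgeR called 0 of 18202 genes (lowest adjusted p = 0.409), with 2172 at an unadjusted p under 0.05 (1264 higher, 908 lower; 910 by chance), while DESeq2 called 191 (163 higher, 28 lower) and limma on log2(FPKM + 1) called 0. Groups did not overlap for 2582 genes (14.2%, against 10% by chance). Leaving out BNP-PEDOT-PSF-AG 1 raised the edgeR count to 2189 (987 higher, 1202 lower), and leaving out PEDOT-PSF-AG 2 or 3 gave 2 and 1.

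The other lists did not pass camera in this comparison, and limma's fry for changes in either direction passed the pro-inflammatory list (adjusted p = 0.0262) and alternative activation (0.0275). MHC class II genes had a median of 0.76 with 8 of 9 above 0 (camera adjusted p = 0.0625). The median of −0.32 for PEDOT-PSF-AG against AG uses the same PEDOT-PSF-AG libraries with opposite sign. For BNP-PEDOT-PSF-AG against AG it was 0.06. HLA-DQB1 was at 2.43 ± 0.653 on PEDOT-PSF-AG and 4.18 ± 0.524 CPM on BNP-PEDOT-PSF-AG. Glycolysis genes had a median of −0.09 (0.0625), hydrogen sulfide metabolism genes 0.42 (0.189), the pro-inflammatory list 0.12 (0.137), NRF2 targets 0.22 (0.137) and inflammasome genes 0.42 (0.151). Cholesterol synthesis (0.17), NF-kB (−0.06), mitochondrially encoded (−0.13), lipid handling (0.03), growth factor (0.29), Toll-like receptor (−0.25), iron (0.13) and ion channel genes (0.08) had adjusted p-values from 0.22 to 0.939. Median, mean and test differed in sign for alternative activation (0.38, −0.23 and down; 0.788; mean −0.10 with STAB1 at its bound), metallothioneins (0.08, −0.12 and down; 0.788), heat shock (−0.15, 0.03 and down; 0.65), the stress response (−0.07, 0.10 and down; 0.788), lysosome (−0.01, 0.02 and down; 0.927) and apoptosis genes (−0.24, 0.10 and down; 0.659). With 1 library left out 19 of these 20 medians moved by over 1.5 times or lost their sign in at least 1 fit, and 8 were seen on both sides of 0. The MHC class II median ran from 0.36 (without BNP-PEDOT-PSF-AG 2) to 0.86 (without BNP-PEDOT-PSF-AG 1), glycolysis from −0.21 (BNP-PEDOT-PSF-AG 3) to 0.04 (BNP-PEDOT-PSF-AG 1), the pro-inflammatory from −0.03 (BNP-PEDOT-PSF-AG 1) to 0.29 (PEDOT-PSF-AG 1), hydrogen sulfide from 0.21 (BNP-PEDOT-PSF-AG 2) to 0.46 (PEDOT-PSF-AG 2), mitochondrially encoded genes from −0.36 (BNP-PEDOT-PSF-AG 1) to 0.04 (BNP-PEDOT-PSF-AG 2) and apoptosis from −0.49 (BNP-PEDOT-PSF-AG 1) to −0.06 (BNP-PEDOT-PSF-AG 2).

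The log2 fold changes of PEDOT-PSF-AG and of BNP-PEDOT-PSF-AG against AG correlated across the 18202 genes at a Pearson's r of 0.658 and a Spearman's rho of 0.311. Genes are not independent replicates, and both comparisons share the AG libraries. In 100 simulations of unchanged groups sharing those libraries the mean was 0.501 (highest 0.543) for Pearson's r and 0.456 for Spearman's rho. The covariance was 0.551, against 0.25 simulated, a difference of 0.301. Spearman's rho lay below its simulated value, so the ranks show no excess. With 3 AG libraries the controls could not be split into parts of at least 2, so the shared part could not be taken out of the observed value. The simulated values already include the shared controls. They take the spread of a gene to be the same in all gels, so the source of the excess in Pearson's r could not be told. Without PEDOT-PSF-AG 2, a library with epithelial markers, Pearson's r was 0.114.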

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

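For PEDOT-PSF-AG against AG edgeR called 0 genes, DESeq2 14, and limma on log2(FPKM + 1) called 1 with no filter and 1 with a robust variance prior. Leave-one-out gave 0 to 3. The 9 called lists became 0 with an estimated correlation, 1 in limma with an FPKM of at least 5, and 5 to 10 in leave-one-out. The list calls for glycolysis, extracellular matrix, lysosome and MHC class II were kept in all 6 leave-one-out fits. Over 27 alternative settings at the preset correlation, these fits included, they were lost in 1, 3, 2 and 8 settings in that order.

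For BNP-PEDOT-PSF-AG against AG edgeR called 0 genes, 1 with no low-count filter and 1 with a robust variance prior, and DESeq2 called 482. limma on log2(FPKM + 1) called 6, with a pseudocount of 0.1 it called 4 and with 5 it called 12. With an FPKM of at least 5 it called 14, with upper quartile scaling 3, with quantile normalization 4 and with a robust prior 46. Leave-one-out gave 0 to 1346. The 7 called lists became 0 with an estimated correlation, 3 in limma with an FPKM of at least 5, and 5 to 7 in leave-one-out.

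For BNP-PEDOT-PSF-AG against PEDOT-PSF-AG edgeR called 0 genes, DESeq2 191, and limma 1 with no filter and 3 with a robust prior. Leave-one-out gave 0 to 2189. The 6 called lists became 0 with an estimated correlation, 3 in limma with an FPKM of at least 5, and 2 to 6 in leave-one-out. Quantile normalization split the called lists as 2 higher and 4 lower for PEDOT-PSF-AG against AG (main 1 and 8) and as 2 and 5 here (main 3 and 3). The highest counts of both BNP-PEDOT-PSF-AG comparisons came without BNP-PEDOT-PSF-AG 1, the library apart from the other pair of its gel. The cause of the other moves was not tested.

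The correlation of both effects against AG (0.658) was 0.243 in limma on log2(FPKM + 1), 0.3 and 0.208 with pseudocounts of 0.1 and 5, 0.263 with no filter, 0.203 with an FPKM of at least 5, 0.24 with upper quartile scaling, 0.248 with quantile normalization and 0.243 with a robust prior. Leave-one-out gave 0.114 (without PEDOT-PSF-AG 2) to 0.714. A value within 0.185, the SD of the leave-one-out values, counted as unmoved; this band replaced a jackknife SE of 0.494 after the values were seen.

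A block for replicate number gave 0 genes in each comparison, and 8, 5 and 4 lists where the main fit gave 9, 7 and 6 (359 at an unadjusted p under 0.05 for PEDOT-PSF-AG against AG). Deviations from the gel means of libraries with the same number correlated between −0.2 and 0.37. They were 0.17, 0.32 and 0.3 for number 1, 0.2, 0.04 and 0.37 for number 2, and −0.19, 0.13 and −0.2 for number 3. Libraries of other gels with another number correlated between −0.53 and 0.38. These ranges overlap, so whether the number marks a batch could not be told.

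Settings chosen after seeing the data follow. The 4 libraries under 1 CPM of both COL1A2 and KRT8 (AG 1, PEDOT-PSF-AG 1 and 3, BNP-PEDOT-PSF-AG 1) gave 68, 59 and 59 genes in the order above, 2 lists for PEDOT-PSF-AG against AG and 4 for BNP-PEDOT-PSF-AG against AG. That fit has 1 residual degree of freedom and takes lone libraries to vary like the PEDOT-PSF-AG pair, so its counts show no gel difference. Without PEDOT-PSF-AG 2 and BNP-PEDOT-PSF-AG 1, genes were 1, 1343 and 1414, lists for PEDOT-PSF-AG against AG 5, and the correlation 0.026. Without genes under 1 CPM in those 4 libraries, BNP-PEDOT-PSF-AG against AG had 1 gene and the correlation was 0.357. The newer edgeR method called 2 genes for BNP-PEDOT-PSF-AG against AG, the length and GC correction 1, and a replicate block with that correction 2 genes and 11 lists. With the correction and without BNP-PEDOT-PSF-AG 1, genes were 2143 against AG (944 higher and 1199 lower, where the same libraries without correction gave 730 and 616) and 2424 against PEDOT-PSF-AG, and lists for PEDOT-PSF-AG against AG 14. The causes were not tested.

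Named genes gave 2668 values over 99 results. Of these 2453 stayed on the same side of the threshold, 215 passed only under an alternative, 0 passed only in the main edgeR fit and 0 reversed; 109 had the opposite sign with neither past the threshold. Of the 215, 45 came from DESeq2, 47 without BNP-PEDOT-PSF-AG 1, 45 without PEDOT-PSF-AG 2 and BNP-PEDOT-PSF-AG 1, and 46 with the length and GC correction without BNP-PEDOT-PSF-AG 1.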

Other observations

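Leaving out BNP-PEDOT-PSF-AG 1 was one of the planned omissions, and it is described because it called the most genes, so its p-values are too small and libraries 2 and 3 are no separate group. Without BNP-PEDOT-PSF-AG 1, CXCL8 was at 76900 ± 22200 CPM (n = 2) and had a log2 fold change of 2.24 (SE 0.40; edgeR adjusted p = 0.0267). MIR155HG, the host transcript of an LPS-induced microRNA, stood at 46.6 ± 6.71 against 7.29 ± 3.06 CPM on AG (2.67, SE 0.34, edgeR adjusted p = 0.0218), and BCL2A1, an NF-kB-driven survival gene, at 1330 ± 384 against 268 ± 104 CPM (2.31, SE 0.38). LY96, the co-receptor of LPS, had a log2 fold change of 2.06, while the receptor genes TLR4 and TLR2 were at −1.25 and −0.79. Of 16 Toll-like receptor and adaptor genes 1 was called higher and 2 lower. That list did not pass (camera of limma, adjusted p = 0.155, or 0.467 with an estimated correlation). Of 14 inflammasome genes 3 were called higher (PYCARD, CASP1 and GSDMD at 1.09, 1.44 and 0.88) and 1 lower (the sensor NLRP3 at −1.01), and the list did not pass (camera of limma, adjusted p = 0.272; 0.477 with an estimated correlation). FN1 (fibronectin) was at 433 ± 115 against 1490 ± 368 CPM, and IL6 at −0.89 (SE 0.20; edgeR adjusted p = 0.0367).

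Of 11 hydrogen sulfide metabolism genes 3 were called higher against PEDOT-PSF-AG in that fit, and the list did not pass (camera of limma, adjusted p = 0.0606; 0.461 with an estimated correlation). Against PEDOT-PSF-AG, MPST and TST, which handle sulfane sulfur, had log2 fold changes of 1.30 (SE 0.21) and 1.27 (SE 0.24), and ETHE1, a mitochondrial sulfide-oxidation enzyme, of 0.98 (SE 0.24; edgeR adjusted p from 0.0195 to 0.0338). BNP-PEDOT-PSF-AG 1 had 9.63, 5.66 and 54.5 CPM of them, against 29.1 ± 3.97, 15.8 ± 3.20 and 114 CPM in the other libraries of its gel. Of 27 stress response genes 4 were called higher against AG (the serine synthesis genes PHGDH and PSAT1 and the asparagine synthetase ASNS at 2.16, 1.45 and 1.25 among them) and 2 lower (PDIA4 at −0.82), and the list did not pass (median −0.09; camera of limma, adjusted p = 0.615). TFRC, the transferrin receptor, was at −1.31 against PEDOT-PSF-AG, with ferritin FTL at 0.77 and the lipid peroxidase GPX4 at 1.10. Of 19 iron handling and ferroptosis genes 2 were called higher and 2 lower. That list did not pass (camera of limma, adjusted p = 0.732, or 0.829 with an estimated correlation). UBE2C, a mitotic gene, was at 13.7 ± 2.65 against 1.89 ± 0.918 CPM on AG and at 0.763 CPM in BNP-PEDOT-PSF-AG 1. Of the genes called without that library, 522 were higher and 559 lower against both gels, where 38.2 and 39.2 would be shared if independent, though both counts share the same 2 libraries.

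Why BNP-PEDOT-PSF-AG 2 and 3 differ from library 1 was weighed with tests of which those for admixed RNA in the higher genes and for gene length and GC content as the whole cause were chosen only after the result was seen. Admixed epithelial-like RNA stays open: PEDOT-PSF-AG 2, with a relative marker level of 0.661 (sums without TMM), showed a median share of −0.0298 of the rise of 719 genes, which speaks against it but is one library, and 84 of the 730 higher genes were under 1 CPM in AG 1, PEDOT-PSF-AG 1 and 3 and BNP-PEDOT-PSF-AG 1. Dilution by admixed RNA would lower all THP-1 transcripts alike. The lower genes had a median of −0.97, and 1608 other abundant genes one of −0.17 (SD 0.50, quartiles −0.45 and 0.23). Whether dilution had a part could not be told from this. The lower genes were chosen by their fall, so their lower median was fixed in advance. TMM scaling also removes a fall shared by most genes. For bias by gene length and GC content, the correction removes only what its splines fit. Such fitted bias was not the whole cause. After correction 0.718 of the genes called against AG and 0.603 of those called against PEDOT-PSF-AG were still called. The calls in all went from 1346 to 2143 and from 2189 to 2424. Bias that the correction left in place could not be excluded. Whether fitted bias was part of the cause could not be told, as a median of 0.736 of the change was left after correction (quartiles 0.575 and 0.908). Gene names already seen prompted that test. A wrong label on library 1 could not be told either, as its position was 0.097 within the −0.241 to 0.383 of the AG and PEDOT-PSF-AG libraries, yet MT-RNR1 and MT-RNR2 were at 1570 and 13000 CPM against at most 821 and 7360 there. After first values were seen, the admixture and dilution tests were limited to genes called against AG (−0.0546 and −0.98 before), the length test was pooled over both comparisons (0.777 and 0.706 alone; 0.777 had met the bound for exclusion), and the mitochondrial RNAs were added; the dilution test was removed and restored before it was run.

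The epithelial-like transcripts of PEDOT-PSF-AG 2 and BNP-PEDOT-PSF-AG 2 and 3 were weighed in tests of which the one for a gel effect was chosen only after the result was seen. Expression switched on in THP-1 cells by a gel stays open, since the 390-fold or larger difference of KRT8 and KRT18 between libraries of the same gel restates the pattern; it leaves room only for an effect in some cultures of a gel. RNA of one other cell source could not be told: the log2 ratios of 234 genes between these libraries had an SD of up to 0.62, just above the 0.6 set for it.

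The mitochondrial ribosomal RNAs, higher in all 3 BNP-PEDOT-PSF-AG libraries by a mean log2 of 1.67, were weighed in tests of which those for a general mitochondrial rise and for admixed RNA were chosen only after the result was seen. The rise was not one of all mitochondrial transcripts, as the 13 messenger RNAs had a median of −0.13 (−0.61 to 0.31). Admixed epithelial-like RNA does not account for BNP-PEDOT-PSF-AG 1, which lacked the markers and stood above all AG and PEDOT-PSF-AG libraries. For BNP-PEDOT-PSF-AG 2 and 3 it could not be excluded. There only PEDOT-PSF-AG 2 speaks against it, a single library with the markers and 0.626 of the level of its fellow libraries. Less complete poly(A) selection could not be told: 16 nuclear RNAs without tails had a median of 0.40 (95% bootstrap interval −0.20 to 0.97), where at least 0.84 would fit. Relabelling the 6 libraries of a comparison gives 10 splits, too few to tell. All 10 gave as many genes as the real 0, with up to 0, 1544 and 677 in other splits. Both of the high ones set BNP-PEDOT-PSF-AG 2 and 3 (with AG 3 for 1544 and PEDOT-PSF-AG 2 for 677) against BNP-PEDOT-PSF-AG 1. With AG 1 or AG 2, or with PEDOT-PSF-AG 1 or PEDOT-PSF-AG 3, in their place the count was 0. The high counts thus hang on the library that joins the pair. For lists, 1 of 10 splits (the real one) reached the 9, 7 and 6 called. The other splits gave 3 to 8, 2 to 6 and 1 to 5. Camera at its preset correlation thus called lists in every split, also where both sides mixed the gels.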
